A study of Mus musculus with 48 samples.

How the data were processed

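Poly(A) RNA of snap-frozen brown, subcutaneous and visceral fat was sequenced in 48 libraries: 3 depots, 2 genotypes (Cth+/+ and Cth-/-) and 2 diets (control and cystine-free, 6 days), with 4 libraries in each of the 12 groups. The labels name the visceral samples EFAT and the subcutaneous samples SFAT. The deposited table holds expected counts per gene from RSEM, not scaled, for 47729 genes with versioned Ensembl IDs, of which 14624 had 0 reads in every library. Per the labels the authors used FastQC, STAR, Picard and RSEM with the build mm10; their versions, and the annotation release, are not given in the sources used here. Between 5.31 and 8.16% of the values of a library were not whole, and counts were rounded to whole numbers for the tests. Without the version suffix 47224 IDs matched the GENCODE M21 annotation (39106 with it), from which coordinates (GRCm38) were taken; gene types are those of the table. The table held 27 symbols turned into dates, which were tested and not named, and 128 symbols on more than 1 line, which were kept apart by ID.

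Genes were tested by depot with the edgeR quasi-likelihood F-test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on all 16 libraries of the depot in 4 groups, with TMM scaling and filterByExpr (minimum count 10, minimum total 15). The 5 comparisons of a depot were the diet in Cth-/- mice, the diet in Cth+/+ mice, the genotype on each diet and the genotype by diet interaction. Differences of the diet response between depots in Cth-/- mice were tested in a fit of all 48 libraries in 12 groups. A gene was counted at a Benjamini-Hochberg adjusted p under 0.05, and p-values are two-sided. Log2 CPM values for list tests used a prior count of 2. DESeq2 1.42.0 was the second tool, and Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for tables, exact tests and plots. The comparisons, tests, gene lists, named-gene rule and these alternatives were chosen before the data were examined.

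Of 33 gene lists fixed in advance, those with at least 5 tested genes were tested by camera with an inter-gene correlation of 0.01, adjusted over the lists and comparisons of a depot. Beside it stand camera with an estimated correlation, fry, the members past the test over all genes, and the members past it when adjusted over the list alone. Camera passed for 64 of 135 list tests in BAT, 82 of 160 in SFAT and 62 of 165 in EFAT, and 4 of these held with an estimated correlation: extracellular matrix genes in SFAT for the diet in Cth-/- mice, the genotype on the cystine-free diet and the interaction, and clock genes in SFAT for the genotype on the control diet. Fry passed 121 list tests, 107 of them among those past camera. A list of 200 BAT-enriched genes per white depot was taken from Cth+/+ control libraries (highest BAT over depot ratio, adjusted p under 0.05, at least 20 CPM in BAT, members of the muscle list left out). Other muscle genes such as Ttn stayed in it: 28 of 200 genes (SFAT) and 24 of 192 tested (EFAT) correlated at 0.5 or more with the muscle list over the BAT libraries, a count added after the data were seen. Overlaps between depots were tested with Fisher's exact test.

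Genes were named by a fixed rule. Always named were Cth, thermogenic, stress-response, lipid and adipokine genes chosen in advance (in the genotype comparisons only those that passed, and Cth). For each list described, up to 4 passing members with the largest change and a mean of at least 1 CPM were named, with members that did not pass as examples. Last came the 8 largest rises and the 8 largest falls among passing genes with a mean of at least 5 CPM and no overlap between the libraries of the groups (5 each way and no overlap condition for interactions and depot differences), leaving out predicted genes and pseudogenes. Some genes that this rule names are not reported here. The Epcam, Crisp1, Adam7, Dbp and Zic1 levels given, the genes shared by all depots, and the short lists of all passing genes in the diet comparison of Cth+/+ mice and the genotype comparison on the control diet were chosen after their values were seen.

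The alternatives fixed in advance were RLE scaling, no low-count filter, robust dispersion, DESeq2, a fit of only the 2 groups compared, each replicate left out in turn and, for the depot differences, the replicate number as a block. Added after the data were seen were the library set, doubted libraries and other cell types. Reads of the pseudogene Gm43512 separated the libraries into set A (under 0.1 CPM) and set B, with 7 set B libraries in each depot: replicates 1, 2, 10, 11, 12, 14 and 20 in BAT, 3, 4, 7, 10, 12, 14 and 20 in SFAT, and 1, 2, 4, 15, 17, 18 and 20 in EFAT. The set was tried as a term and as 2 separate fits, in which 5 groups held a single library and 1 group none. Between the sets 2929 genes differed in BAT, 1688 in SFAT and 368 in EFAT, and 7.41, 11.0 and 22.8% of these were pseudogenes, against 4.55, 4.86 and 4.46% of the genes tested (Fisher's exact p = 5.1e-15, 1.8e-27 and 1.3e-36). Doubted libraries were those of replicates 10, 12 and 20 in BAT (TMM factor under 0.85), 14 (B cell genes) and 20 (mitochondrial transcripts) in SFAT, and 2, 11 and 14 in EFAT (almost no epithelial transcripts, and in 11 also brown fat and muscle transcripts). The covariate was the mean log2 CPM of the muscle list in BAT and of the epithelial list in SFAT and EFAT.

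Mitochondrial transcripts took 21.8 to 45.7% of counts in BAT, 7.06 to 31.3% in SFAT and 4.82 to 14.7% in EFAT. A count of 0 was read as up to 3 counts, and ratios of few counts have exact (Clopper-Pearson) 95% intervals on the summed reads; both cover counting error only. Replicates were checked for copies: the closest of 72 pairs differed by a chi-square of 15.8 per gene and 0 pairs were identical. Correlations of the residuals by replicate number ran from -0.11 to 0.49, with medians of 0.179 (BAT and SFAT), 0.0295 (BAT and EFAT) and 0.122 (SFAT and EFAT) against -0.00366, -0.00544 and -0.0114 for other numbers. A number matched itself best in 6, 4 and 4 of 16 cases, where chance gives 1, which shared animals may give. The labels do not state this, and the fit with the block stands beside the fit without it.

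The pipeline was tested on simulated data with the depth and spread of these libraries. Genes were drawn independently, without a library set or other tissue, so the rates do not cover errors from those sources. For the diet comparison in Cth-/- mice it called 22.4, 72.7 and 84.8% of genes changed 1.5, 2 and 4 times in BAT (14368 genes tested), 21.2, 55.4 and 77.3% in SFAT (16304) and 17.9, 47.8 and 65.1% in EFAT (16979). False calls were 3 of 123, 6 of 109 and 5 of 92, with 0 in a comparison without change in each depot. Far fewer genes were changed than the real comparison called (2617 in BAT). The adjustment is stricter then, so the rates may not hold for that comparison. Protein, isoforms, body weight and food intake were not analysed here.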

Results

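Poly(A) RNA was sequenced from 3 fat depots of male mice that carry or lack Cth, the gene of cystathionine gamma-lyase, the enzyme that makes cysteine from cystathionine. The depots were brown fat (BAT), subcutaneous white fat (SFAT) and visceral white fat (EFAT). Wild-type mice (Cth+/+) and knockout mice (Cth-/-) ate a control diet (CTRL) or a cystine-free diet (CysF) for 6 days. The diet comparison asked how fat tissue responds when dietary cystine is withdrawn, with and without the enzyme, and the stated subject of the study is thermogenesis of fat tissue. The design gave 12 groups of 4 libraries, 48 in all. Total expected counts per library ranged from 22.1 to 46.0 M in BAT, 16.2 to 39.0 M in SFAT and 18.7 to 36.1 M in EFAT (M for mega). Gene levels are given as CPM (reads relative to the library total, scaled by TMM), as mean ± SD with n = 4 libraries per group, and changes as log2 fold changes ± SE. The labels give each library a number, written below as replicate 1 to 20, but do not state that each number is a separate animal or that a number is the same animal in each depot, so p-values measure the spread between these samples.

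Cth (ENSMUSG00000028179, GRCm38 chromosome 3, 157894248 to 157925077, minus strand) was measured first, in every library. The 24 libraries of Cth-/- mice held 0 to 6 Cth reads each and the 24 libraries of Cth+/+ mice held 8 to 389. Mean Cth in Cth+/+ mice on the control diet was 0.773 ± 0.524 CPM in BAT, 9.53 ± 1.91 CPM in SFAT and 12.1 ± 1.57 CPM in EFAT. On the control diet Cth fell in Cth-/- mice by a log2 fold change of -7.67 ± 0.53 in SFAT and -7.18 ± 0.57 in EFAT. In BAT 88 reads in Cth+/+ against 1 read in Cth-/- gave a ratio of 97.9 (95% interval of the counts 17.1 to 3910) on the control diet, and 81 against 1 gave 103.0 (18.0 to 4116) on the cystine-free diet. Cth did not change with diet in Cth+/+ mice beyond the spread between libraries, with log2 fold changes of -0.04 ± 0.46 in BAT, -0.41 ± 0.33 in SFAT and -0.06 ± 0.40 in EFAT.

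**Figure D1:**
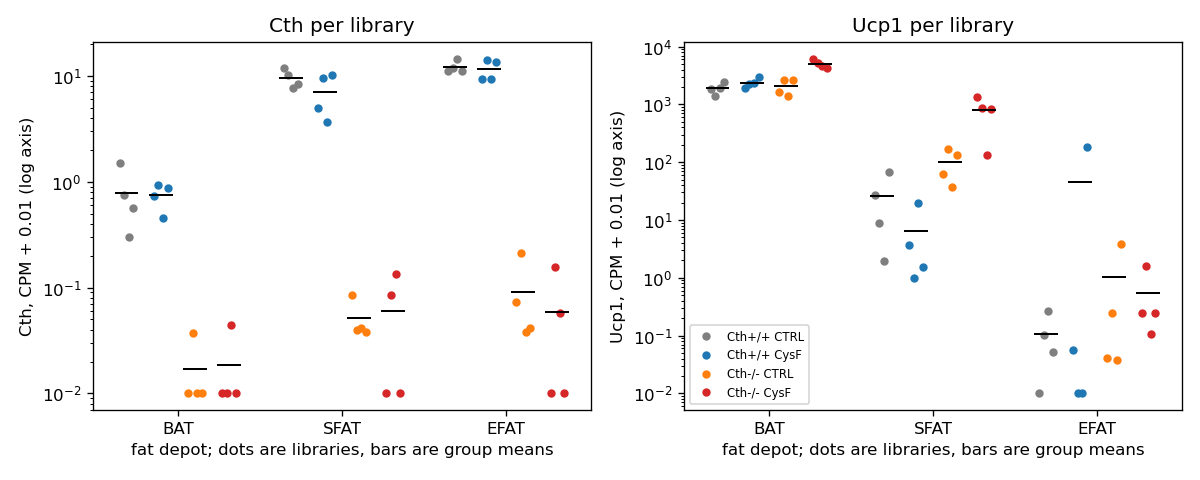
Cth (left) and Ucp1 (right) in each of the 48 libraries, as CPM with 0.01 added on a log axis, by depot and group; dots are libraries and bars are group means. Cth reads were 0 to 6 in each Cth-/- library, and Ucp1 reached 4225 to 6069 CPM in BAT and 135.3 to 1337 CPM in SFAT of Cth-/- mice on the cystine-free diet.

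The cystine-free diet changed genes in all 3 depots of Cth-/- mice. In Cth-/- mice 2617 of 14528 tested genes changed in BAT (1135 higher, 1482 lower), 4208 of 16555 in SFAT (1957 higher, 2251 lower) and 4976 of 17248 in EFAT (2507 higher, 2469 lower). In Cth+/+ mice the same diet gave 12 genes in BAT, 11 in SFAT and 0 in EFAT. The test of the difference between the genotypes passed for 932 genes in BAT, 3600 in SFAT and 1792 in EFAT.

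**Figure D2:**
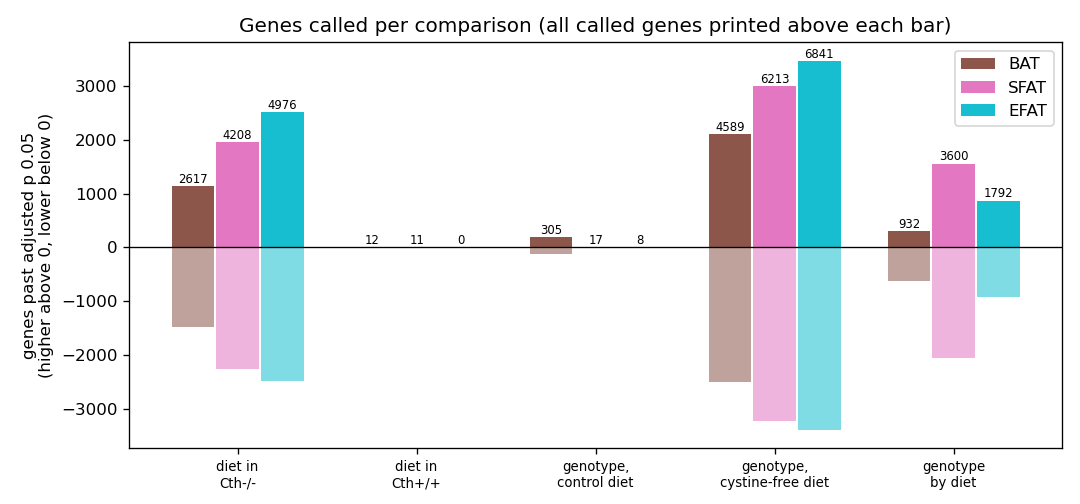
Number of genes past an adjusted p of 0.05 in each of the 15 comparisons by depot. Bars above 0 are genes higher and bars below 0 genes lower. Diet comparisons are cystine-free over control diet, and genotype comparisons are Cth-/- over Cth+/+ mice. For the interaction, higher means a higher log2 change in Cth-/- mice. The diet in Cth-/- mice gave 2617 genes in BAT, 4208 in SFAT and 4976 in EFAT, against 12, 11 and 0 in Cth+/+ mice.

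In BAT of Cth-/- mice, the cystine-free diet raised Ucp1, the uncoupling protein of brown fat mitochondria (ENSMUSG00000031710, chromosome 8, 83290352 to 83298452, plus strand), from 2089 ± 657 to 4981 ± 813 CPM (log2 fold change 1.25 ± 0.22, adjusted p = 0.0016). Leptin (Lep), an adipocyte hormone, fell by a log2 fold change of -3.77 ± 0.60. Extracellular matrix genes fell together: 19 of 33 members fell and 1 rose, with a median of -1.05 (camera adjusted p = 3.2e-27; adjusted p = 0.062 with an estimated correlation; 23 lower and 1 higher when adjusted over the list alone). The fibrillar collagen genes Col3a1 (-3.12 ± 0.23), Col1a1 (-2.94 ± 0.34) and Col1a2 (-2.45 ± 0.24) and the basement membrane collagen gene Col15a1 (-2.78 ± 0.18) were among them, with adjusted p from 3.4e-07 to 6.7e-05. The largest rises were Cyp2b10, a cytochrome P450 (6.26 ± 0.44; ENSMUSG00000030483, chromosome 7, 25897620 to 25926624), the lipid transporter Mfsd2a (6.16 ± 1.03), the glucocorticoid-induced chaperone partner Fkbp5 (3.02 ± 0.44) and the GDNF receptor gene Gfra1 (2.75 ± 0.29). Next came Gmpr (2.59 ± 0.41), Hcn2 (2.32 ± 0.34), Cyp1a1 (2.26 ± 0.44) and Myrip (2.26 ± 0.22).

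Of 23 thermogenic genes in BAT, 6 rose and 1 fell (adjusted over the list alone, 12 and 1; camera adjusted p = 0.0018, adjusted p = 0.40 with an estimated correlation). The members that rose included the fatty acid transporter Slc27a2 (1.28 ± 0.33) and the nuclear receptor Esrrb (1.73 ± 0.36), and the member that fell was the beta-3 adrenergic receptor Adrb3 (-1.82 ± 0.21). Dio2 (2.10 ± 0.79, adjusted p = 0.078), Elovl3 (0.64 ± 0.25, 0.090), Ppargc1a (0.80 ± 0.53, 0.32) and Cidea (-0.04 ± 0.11, 0.85) did not pass. Glucocorticoid and fasting response genes rose in 10 of 18 cases and fell in 1 (adjusted over the list alone, 14 and 1; median 0.98, camera adjusted p = 1.2e-08, adjusted p = 0.11 with an estimated correlation). Among them were Fkbp5, Hif3a (2.26 ± 0.55) and the cell cycle inhibitor Cdkn1a (1.33 ± 0.28). Fatty acid oxidation genes rose in 8 of 29 cases with none lower (adjusted over the list alone, 9; camera adjusted p = 1.2e-04, adjusted p = 0.46 with an estimated correlation). One was the carnitine palmitoyltransferase Cpt1a (0.63 ± 0.17). Nuclear genes of oxidative phosphorylation rose in 4 of 66 cases (adjusted over the list alone, 3; median 0.25, camera adjusted p = 1.3e-05, adjusted p = 0.56 with an estimated correlation).

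The triglyceride lipase Pnpla2 rose in BAT of Cth-/- mice (0.60 ± 0.13), and Lipe (-0.04 ± 0.11), Fasn (-0.22 ± 0.17), Scd1 (-0.80 ± 0.28) and Adipoq (0.34 ± 0.14) did not pass. Among 24 lipogenic genes 7 fell and 2 rose (adjusted over the list alone, 8 and 3; camera adjusted p = 0.022, adjusted p = 0.56 with an estimated correlation). Scd2 was at -2.49 ± 0.40 and the acetyl-CoA synthetase Acss2 at -2.18 ± 0.21. Of 22 cholesterol synthesis genes 9 fell and 1 rose (adjusted over the list alone, 14 and 1; camera adjusted p = 2.5e-06, adjusted p = 0.42 with an estimated correlation). These included Insig1 (-1.87 ± 0.19) and Mvd (-1.78 ± 0.34). ATF4 target genes went both ways, 7 higher and 6 lower of 37 (adjusted over the list alone, 9 and 7). The glutathione-degrading Chac1 rose (1.29 ± 0.33) and the proline synthesis gene Pycr1 fell (-2.52 ± 0.66). Atf4 (0.48 ± 0.18), Ddit3 (-0.03 ± 0.26), Asns (-0.07 ± 0.24), Fgf21 (-0.02 ± 0.51), Gdf15 (-0.23 ± 0.62) and the cystine transporter gene Slc7a11 (-2.84 ± 1.04) did not pass.

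Markers of other cell types moved with the diet in BAT of Cth-/- mice. Macrophage genes fell in 10 of 17 cases (adjusted over the list alone, 13; camera adjusted p = 7.1e-06, adjusted p = 0.40 with an estimated correlation; Adgre1 -1.54 ± 0.30, Mrc1 -1.26 ± 0.20). Fibroblast and preadipocyte genes fell in 9 of 15 (adjusted over the list alone, 10; camera adjusted p = 2.0e-09, adjusted p = 0.099 with an estimated correlation; Pi16 -2.18 ± 0.26, Lum -1.92 ± 0.16). Interferon response genes fell in 5 of 20 (adjusted over the list alone, 5; adjusted p = 0.47 with an estimated correlation). Proliferation genes fell in 7 of 18 (adjusted over the list alone, 10; adjusted p = 0.40 with an estimated correlation; Mki67 -5.07 ± 0.68). Skeletal muscle genes fell in 11 of 18 cases (adjusted over the list alone, 17; median -3.07, camera adjusted p = 2.4e-08, adjusted p = 0.42 with an estimated correlation). The muscle actin Acta1 was 197 ± 123 CPM in Cth+/+ mice on the control diet, 272 ± 251 on the cystine-free diet, 87.3 ± 59.9 in Cth-/- mice on the control diet and 7.55 ± 8.96 on the cystine-free diet. Among the largest falls of all genes, Casq1 (-4.85 ± 0.99) and Pvalb (-3.99 ± 0.94) were muscle genes. The other largest falls were Fer1l6 (-3.87 ± 0.28) and the proton channel gene Hvcn1 (-2.92 ± 0.34). Fer1l6 correlated at 0.826 with the muscle list over the BAT libraries. That correlation includes the differences between groups, so it cannot decide whether the fall of Fer1l6 is separate from that of the muscle genes. With the muscle score as a covariate 862 genes passed in place of 2617. The libraries fell into 2 sets, A and B, that reads of a pseudogene separate. With the set as a term 2993 genes passed, within set A 1775, and within set B, with 1 library of this group on the cystine-free diet, 333. Within set A Asns passed as higher (0.62, adjusted p = 0.027). The count was 1938 without the doubted libraries of BAT, 1696 without replicate 14 (Cth-/- control) and 1695 without replicate 17 (Cth-/- cystine-free).

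In SFAT of Cth-/- mice the diet raised Ucp1 from 99.7 ± 61.0 to 797 ± 496 CPM (3.00 ± 1.01, adjusted p = 0.039), and the 4 libraries on the cystine-free diet lay at 1337, 878.5, 135.3 and 836.6 CPM. The direction held in all 18 alternatives, but the call ended in 11 of them (adjusted p from 0.014 to 0.12). Those were among others the fits without replicate 12, 13, 14, 15, 16, 17 or 20 (0.026 to 0.099 over the 8 replicates left out in turn), within set A (2.38) and within set B (4.06), which held 1 library of the cystine-free group. Thermogenic genes rose in 14 of 22 cases and fell in 1 (adjusted over the list alone, 17 and 2; median 1.42, camera adjusted p = 4.6e-06, adjusted p = 0.38 with an estimated correlation). They included the thyroid hormone-activating deiodinase Dio2 (4.03 ± 0.68), Slc27a2 (3.11 ± 0.62), the fatty acid elongase Elovl3 (2.47 ± 0.68), Cidea (1.31 ± 0.38) and the mitochondrial coactivator Ppargc1a (1.35 ± 0.23). Dio2 passed in all 18 alternatives, Elovl3 in all but 3 (1.25 within set A, 1.97 without replicate 20 and 1.72 without the doubted libraries). Cidea passed in all but 6 (0.77 within set A, 1.04 without the doubted libraries, and without replicate 12, 14, 16 or 20). Nuclear genes of oxidative phosphorylation rose in 51 of 66 cases with none lower (adjusted over the list alone, 57; median 0.73, camera adjusted p = 3.1e-21, adjusted p = 0.38 with an estimated correlation). Among them was cytochrome c (Cycs, 1.02 ± 0.21). Fatty acid oxidation genes rose in 22 of 29 (adjusted over the list alone, 24 higher and 1 lower; camera adjusted p = 1.3e-12, adjusted p = 0.19 with an estimated correlation). Examples were Acot1 (3.28 ± 0.40) and Cpt1b (2.08 ± 0.43). Mitochondrially encoded transcripts rose in 4 of 13 cases (adjusted over the list alone, 12; median 1.25, adjusted p = 0.66 with an estimated correlation). They took 31.3% of counts in replicate 20 against 10.6 to 11.5% in the other libraries of its group.

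A list of the 200 genes with the highest BAT over SFAT ratio, chosen from Cth+/+ mice on the control diet, had 117 genes higher and 0 lower in SFAT of Cth-/- mice on the cystine-free diet (median 0.94). Camera from limma gave p = 2.3e-26, and p = 0.050 with an estimated correlation; fry gave p = 6.0e-04. Without the doubted libraries of SFAT 93 rose and 1 fell, and with the library set as a term 129 rose and 1 fell. Of the 172 members that did not follow muscle genes over the BAT libraries 115 rose and 0 fell. The corresponding list for EFAT, of which 192 genes were tested, had 25 higher and 14 lower (median 0.00), and camera did not pass.

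Other genes that rose in SFAT of Cth-/- mice were Cyp2b10 (6.02 ± 0.63), the medium-chain acyl-CoA synthetase Acsm3 (3.48 ± 0.37), the cytokine signalling inhibitor Cish (2.95 ± 0.56), and Mup19 (2.90 ± 0.55). So did Mrgprg (2.81 ± 0.66), Pnpla2 (0.97 ± 0.13), Asns (0.73 ± 0.13) and Chac1 (1.00 ± 0.27). Sulfur amino acid and glutathione genes rose in 10 of 28 cases with none lower (adjusted over the list alone, 12; camera adjusted p = 9.0e-04, adjusted p = 0.19 with an estimated correlation). These included cystathionine beta-synthase Cbs (1.22 ± 0.25), Oplah (0.90 ± 0.18) and Ahcy (0.81 ± 0.17). Glucocorticoid and fasting genes rose in 11 of 18 (adjusted over the list alone, 12; camera adjusted p = 2.3e-07, adjusted p = 0.19 with an estimated correlation). They included Lcn2 (2.77 ± 0.63), Fkbp5 (2.10 ± 0.33) and the metallothionein Mt2 (1.68 ± 0.36). Lipolysis genes rose in 8 of 18 and fell in 1 (adjusted over the list alone, 8 and 1; adjusted p = 0.26 with an estimated correlation), with Plin5 at 1.57 ± 0.27. Atf4 (0.20 ± 0.11), Ddit3 (0.00 ± 0.18), Fgf21 (-0.15 ± 0.67), Gdf15 (-0.34 ± 0.88), Slc7a11 (-0.19 ± 0.56), Lipe (0.28 ± 0.16), Fasn (0.26 ± 0.36), Scd1 (-0.38 ± 0.33) and Adipoq (0.09 ± 0.12) did not pass.

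Extracellular matrix genes fell in 25 of 33 cases in SFAT with none higher (adjusted over the list alone, 29; median -1.38, camera adjusted p = 1.4e-36, adjusted p = 0.014 with an estimated correlation). Col3a1 (-4.26 ± 0.32), Col1a1 (-4.05 ± 0.46) and Col1a2 (-3.38 ± 0.39) were among the largest falls of all genes, with the potassium channel gene Kcnj14 (-3.28 ± 0.41), Prr32 (-3.38 ± 0.48) and Ms4a4c (-3.40 ± 0.64). Lep fell (-2.00 ± 0.58), a call that ended without replicate 12 or replicate 16 and without the doubted libraries (adjusted p from 0.0013 to 0.061 over 18 alternatives). Interferon genes fell in 17 of 20 cases (adjusted over the list alone, 18; camera adjusted p = 2.1e-09, adjusted p = 0.26 with an estimated correlation; Mx1 -1.85 ± 0.34). Proliferation genes fell in 13 of 22 (adjusted over the list alone, 16; adjusted p = 0.47 with an estimated correlation; Mki67 -2.82 ± 0.48). Fibroblast and preadipocyte genes fell in 12 of 15 with 1 higher (adjusted over the list alone, 13 and 1; adjusted p = 0.26 with an estimated correlation; Pi16 -2.63 ± 0.31). Macrophage genes fell in 8 of 17 (adjusted over the list alone, 11; adjusted p = 0.66 with an estimated correlation; Fcgr1 -2.33 ± 0.47). B cell and lymph node genes fell in 12 of 12 cases (adjusted over the list alone, 12; median -3.84, camera adjusted p = 9.0e-04, adjusted p = 0.63 with an estimated correlation). Cd79a was at -4.72 ± 1.43, and the B cell genes Ighd (-3.85 ± 0.91) and Pax5 (-3.77 ± 1.21) were again among the largest falls. Cd79a had 669 reads in replicate 14 (Cth-/- control), 14 to 44 in the other control libraries and 2 to 14 on the cystine-free diet; without replicate 14 Cd79a was at -2.04 and Pax5 at -1.504, and neither passed. The Cd79a call also ended without replicate 16, 17 or 20 and the Pax5 call without replicate 16, 17, 18 or 20 (adjusted p from 0.0011 to 0.29 and from 0.022 to 0.31 over their alternatives). Epithelial genes rose in 1 and fell in 1 of 9 in SFAT (the same counts adjusted over the list alone; camera adjusted p = 0.72). In all 4997 genes passed in SFAT with the library set as a term, 4605 within set A, 3352 within set B (1 library on the cystine-free diet) and 3523 without the doubted libraries.

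In EFAT of Cth-/- mice the diet raised the acyl-CoA thioesterase Acot3 (6.98 ± 0.88), Acsm3 (4.57 ± 0.55), the imprinted zinc finger gene Zim1 (4.73 ± 0.59), Cnksr2 (4.78 ± 1.09) and Teddm2 (4.57 ± 0.85). It also raised the decoy receptor gene Il22ra2 (3.91 ± 0.60), Rassf6 (3.66 ± 0.53) and thrombospondin 2 (Thbs2, 3.59 ± 0.35). The diacylglycerol acyltransferase Dgat2 (-3.83 ± 0.46) and the monoacylglycerol acyltransferase Mogat2 (-5.71 ± 1.04), which build triglyceride, were among the largest falls. Others were Col15a1 (-4.06 ± 0.35), Odf3l1 (-4.49 ± 0.72), Prnd (-4.09 ± 0.95), Wfdc21 (-3.97 ± 0.63), Ighm (-3.95 ± 0.43) and apelin (Apln, -3.89 ± 0.67). Lipogenic genes fell in 12 of 24 cases and rose in 2 (adjusted over the list alone, 17 and 2; median -1.33, camera adjusted p = 3.5e-04, adjusted p = 0.78 with an estimated correlation). One was ATP citrate lyase Acly (-2.87 ± 0.75). Cholesterol synthesis genes fell in 16 of 23 cases (adjusted over the list alone, 18; median -1.32, camera adjusted p = 1.8e-07, adjusted p = 0.65 with an estimated correlation). One was Insig1 (-2.10 ± 0.50). Adipocyte identity genes fell in 10 of 21 and rose in 1 (adjusted over the list alone, 10 and 2; camera adjusted p = 4.1e-05, adjusted p = 0.65 with an estimated correlation). They included the natriuretic clearance receptor Npr3 (-3.17 ± 0.38), Lep (-2.89 ± 0.43) and caveolin 1 (Cav1, -2.09 ± 0.22). Fasn fell (-2.07 ± 0.66) in a call that ended in 11 of 18 alternatives (adjusted p from 0.0026 to 0.87). These included the fits without replicate 12, 14, 17, 18 or 20, with the library set as a term (-1.32) and within set B (-0.35), which held 1 library on the control diet. Adipoq (-0.21 ± 0.19), Lipe (-0.38 ± 0.17) and Scd1 (-0.29 ± 0.35) did not pass.

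Ucp1 in EFAT of Cth-/- mice had 1, 7, 1 and 122 reads on the control diet and 7, 32, 2 and 5 on the cystine-free diet. Thermogenic genes rose in 5 of 19 cases in EFAT (adjusted over the list alone, 5; camera adjusted p = 0.25, not passed). Examples were the pyruvate dehydrogenase kinase Pdk4 (2.28 ± 0.53), Cox8b (2.11 ± 0.66) and Ppargc1a (1.58 ± 0.36), while Cidea (0.36 ± 0.94) and Dio2 (-1.49 ± 0.79) did not pass and Elovl3 had 1 read in the cystine-free group. Nuclear genes of oxidative phosphorylation fell in 6 of 66 cases and rose in 1 (adjusted over the list alone, 1 and 1; median -0.27, camera adjusted p = 0.0078, adjusted p = 0.88 with an estimated correlation). Pnpla2 (0.86 ± 0.14), Chac1 (1.40 ± 0.30), Slc7a11 (1.499 ± 0.50) and the glutamate-cysteine ligase Gclc (1.00 ± 0.16) rose. Atf4 (-0.16 ± 0.14), Ddit3 (-0.55 ± 0.23), Asns (0.33 ± 0.17), Fgf21 (-0.06 ± 0.71) and Gdf15 (1.00 ± 0.50) did not pass. Of 39 ATF4 target genes 10 rose and 8 fell (adjusted over the list alone, 10 and 8). Glucocorticoid and fasting genes rose in 11 of 18 (adjusted over the list alone, 12; median 1.04, camera adjusted p = 3.4e-07, adjusted p = 0.30 with an estimated correlation; Fkbp5 1.57 ± 0.22, Sgk1 1.43 ± 0.16).

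Extracellular matrix genes fell in 22 of 33 cases in EFAT and rose in 2 (adjusted over the list alone, 25 and 2; median -1.09, camera adjusted p = 4.5e-24, adjusted p = 0.25 with an estimated correlation). Col3a1 was at -3.12 ± 0.18 and Col5a3 at -2.98 ± 0.50. Macrophage genes fell in 8 of 17 (adjusted over the list alone, 8 lower and 1 higher; adjusted p = 0.65 with an estimated correlation; Mrc1 -1.05 ± 0.09). Genes of an epididymis and testis list rose in 4 of 9 cases (adjusted over the list alone, 6; median 4.00, camera adjusted p = 0.045, adjusted p = 0.78 with an estimated correlation). These included Rnase10 (8.05 ± 1.72) and Crisp1 (6.24 ± 1.75). On the cystine-free diet Crisp1 had 212 and 1325 reads in replicates 16 and 20 but 3 in each of replicates 17 and 18, and Adam7 had 3585 and 9525 against 8 and 3. The epithelial marker Epcam was almost absent, at 1 to 12 reads, in replicates 2, 11 and 14. Epithelial genes as a list rose in 1 of 6 cases (1 adjusted over the list alone; camera adjusted p = 0.74). Of the 4 libraries on each diet, 3 on the cystine-free and 1 on the control diet were of set B: with the set as a term 3117 genes passed in place of 4976, within set A 65 and within set B 219, each with a single library on one of the diets. The doubted libraries of EFAT do not include replicates 16 and 20, which held the Crisp1 and Adam7 reads. Without the doubted libraries 3592 genes passed, without replicate 12 (Cth-/- control) 2962 and without replicate 14 (Cth-/- control) 3280. Without replicate 16 (Cth-/- cystine-free) the count was 5886. With those single libraries, within set A neither Acot3 (6.99), Mogat2 (-5.88), Dgat2 (-3.71) nor Lep (-2.82) passed, and within set B Acot3 (5.73), Mogat2 (-3.12) and Lep (-2.36) did not.

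**Figure D3:**
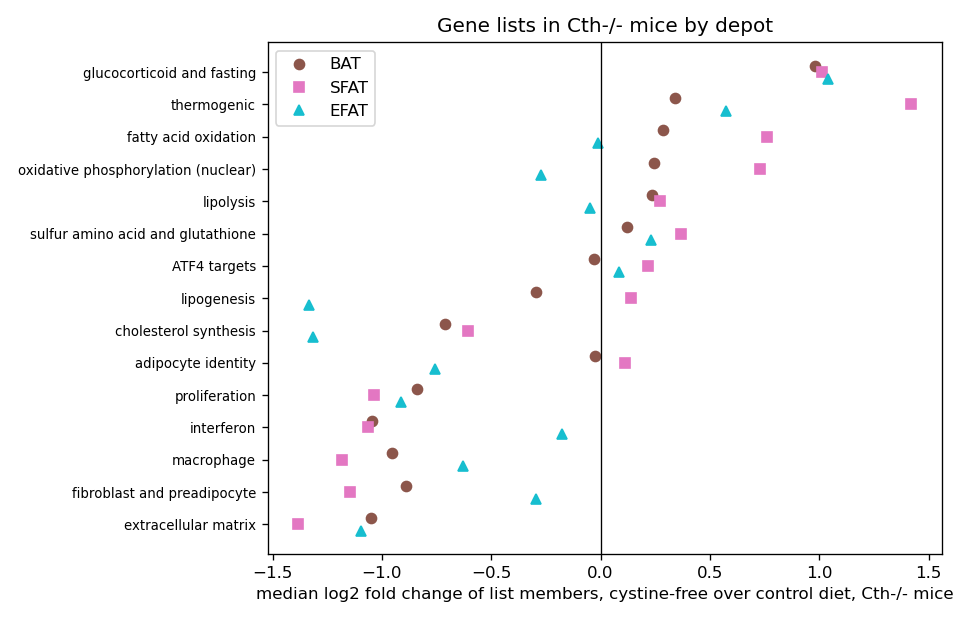
Median log2 fold change of the members of 15 gene lists, cystine-free over control diet in Cth-/- mice; each symbol is the median of one list in one depot. The extracellular matrix list lies at -1.05 in BAT, -1.38 in SFAT and -1.09 in EFAT, and the thermogenic list at 0.34, 1.42 and 0.58.

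**Figure D4:**
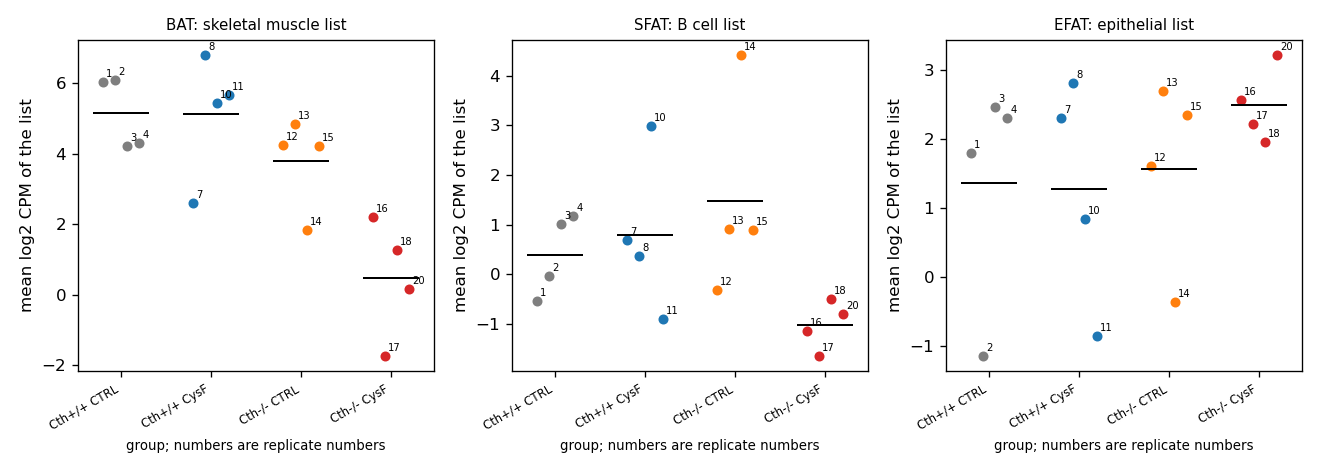
Mean log2 CPM of the skeletal muscle list in BAT, the B cell list in SFAT and the epithelial list in EFAT; each dot is a library with its replicate number and bars are group means. Acta1, a member of the muscle list, averaged 87.3 ± 59.9 CPM in BAT of Cth-/- mice on the control diet and 7.55 ± 8.96 CPM on the cystine-free diet.

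The depots shared diet calls in Cth-/- mice beyond what independent lists would give. The expected counts and Fisher's exact p take the depots as independent, although libraries of equal number may come from the same animal. BAT and SFAT shared 574 genes higher (145.5 expected, Fisher's exact p = 2.9e-236) and 785 lower (191.6 expected). SFAT and EFAT shared 912 higher (293.0 expected) and 1019 lower (336.3 expected). BAT and EFAT shared 315 higher (175.1 expected, Fisher's exact p = 1.2e-28) and 573 lower (233.2 expected). In all 3 depots 251 genes rose and 455 fell of 14124 tested in each, against 22.9 and 30.8 expected, while 182 genes changed in opposite directions between depots. The genes that fell in all 3 depots included Col15a1 (-2.78, -2.84 and -4.06 in BAT, SFAT and EFAT), Col3a1 (-3.12, -4.26 and -3.12), the chemokine Ccl8 (-3.18, -3.28 and -4.09), Mki67 (-5.07, -2.82 and -2.26) and Lep (-3.77, -2.00 and -2.89). Those that rose in all 3 included Mfsd2a (6.16, 3.08 and 3.03), Doc2b (3.19, 2.49 and 2.72), Cish (2.16, 2.95 and 2.74) and Fkbp5 (3.02, 2.10 and 1.57).

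Tests of the difference between depots named the genes whose diet response in Cth-/- mice diverged. Between EFAT and BAT 2976 of 18348 genes differed (1337 with a higher and 1639 with a lower log2 change in EFAT), between EFAT and SFAT 804 (190 and 614) and between SFAT and BAT 397 (246 and 151). Cyp2b10 rose in BAT and SFAT and its change in EFAT was lower (difference -6.25 ± 0.76 from BAT and -5.99 ± 0.80 from SFAT). Nuclear genes of oxidative phosphorylation had a lower log2 change in EFAT than in SFAT in 50 of 66 cases (median difference -1.06, camera adjusted p = 7.2e-45, adjusted p = 0.14 with an estimated correlation). Dio2 (-5.55 ± 1.29), Fasn (-2.38 ± 0.65) and Lipe (-0.72 ± 0.21) were also lower there. Against BAT, EFAT changes were lower for Dgat2 (-4.32 ± 0.54), Mogat2 (-5.06 ± 1.35), Orm3 (-3.81 ± 0.62), Angptl8 (-3.71 ± 1.27) and Atf4 (-0.70 ± 0.21) and higher for Slc7a11 (4.31 ± 1.08). The changes of Ucp1 in SFAT and BAT, 3.00 and 1.25, differed by 1.74 ± 1.59 (adjusted p = 0.70), which did not pass. The 5 largest differences of SFAT over BAT held the muscle genes Mylk4 (5.19 ± 1.43), Casq1 (4.94 ± 1.39), Myh2 (4.78 ± 1.32) and Neb (4.56 ± 1.19) beside Mup19 (5.01 ± 1.27). SFAT changes were lower than those of BAT for Npr3 (-3.09 ± 0.63), the chemokine Cxcl14 (-2.68 ± 0.50) and Loxl1 (-2.13 ± 0.28). The counts were higher with the replicate number as a block (4231 for EFAT and BAT, 2234 for EFAT and SFAT, 892 for SFAT and BAT) and by DESeq2 (3515, 1213 and 623). They were lower without the low-count filter (1949, 528 and 191). With the library set as a term the EFAT differences passed for 1753 genes against BAT and 238 against SFAT, and without the doubted libraries the 3 counts were 1731 (EFAT and BAT), 468 (EFAT and SFAT) and 157 (SFAT and BAT). Without replicate 12 the counts were 1075, 236 and 106 in the same order, and without replicate 17 they were 1520, 178 and 190. For EFAT and BAT the count was 1231 without replicate 14, 1953 without replicate 18 and 3828 without replicate 15. For EFAT and SFAT it was 983 without replicate 15, 202 without 14, 517 without 13, 462 without 16 and 356 without 20. For SFAT and BAT it was 176 without replicate 13, 252 without 15, 180 without 16, 234 without 18 and 179 without 20.

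In Cth+/+ mice the cystine-free diet raised Per2, a clock gene that glucocorticoids also induce, in BAT (2.50 ± 0.40, adjusted p = 0.040) and in SFAT (1.64 ± 0.28, 0.046). In BAT 12 genes passed, 8 higher and 4 lower. Ifi205 (1.78 ± 0.27), Usp2 (1.65 ± 0.27), Snrk (1.10 ± 0.16), Lnx1 (1.06 ± 0.18), Tle3 (0.85 ± 0.15) and Shb (0.77 ± 0.13) rose. Zfp608 (-1.07 ± 0.16), Bahcc1 (-1.06 ± 0.18), Id2 (-1.03 ± 0.18) and Mllt4 (-0.72 ± 0.12) fell. In SFAT 11 genes passed, 9 higher and 2 lower. Fam107a (1.97 ± 0.32), Fkbp5 (1.96 ± 0.33), Hif3a (1.93 ± 0.29), the cell cycle kinase Wee1 (1.39 ± 0.24), Pawr (1.17 ± 0.20), Lrrc8c (0.73 ± 0.12) and Rnf169 (0.54 ± 0.09) rose and Echdc3 (-0.54 ± 0.09) fell. In EFAT edgeR called 0 genes and DESeq2 called 21. An unadjusted p under 0.05 was reached by 678 of 17248 tested genes in EFAT, under the share of 0.05 that no effect would give. In BAT 1424 of 14528 genes reached it and in SFAT 2310 of 16555, above that share. Glucocorticoid and fasting genes were higher as a list in each depot, with medians of 0.73 in BAT, 0.53 in SFAT and 0.51 in EFAT (camera adjusted p = 2.2e-15, 5.0e-14 and 2.5e-18; adjusted p = 0.052, 0.075 and 0.074 with an estimated correlation). In the same order 0, 2 and 0 members passed over all genes and 9, 10 and 8 when adjusted over the list alone.

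Extracellular matrix genes in SFAT of Cth+/+ mice had a median of 0.66 (camera adjusted p = 2.7e-17, adjusted p = 0.13 with an estimated correlation), with 0 members past the test over all genes and 19 when adjusted over the list alone. In BAT their median was 0.43, with 0 and 15 members (adjusted p = 0.25 with an estimated correlation). Interferon genes in SFAT had a median of 0.76, with 0 members over all genes and 15 when adjusted over the list alone (adjusted p = 0.16 with an estimated correlation). Nuclear genes of oxidative phosphorylation had a median of -0.36 with none past either adjustment (adjusted p = 0.40 with an estimated correlation). Ucp1 was 1886 ± 417 CPM on the control and 2367 ± 415 CPM on the cystine-free diet in BAT and 26.2 ± 29.5 and 6.39 ± 8.75 CPM in SFAT. These were log2 fold changes of 0.33 ± 0.22 and -2.05 ± 1.02 that did not pass. Neither did Chac1 (0.08 ± 0.32, -0.65 ± 0.28 and -0.76 ± 0.30 in BAT, SFAT and EFAT), Fgf21 (-1.03 ± 0.38, -0.92 ± 0.66 and -0.83 ± 0.73) or Lep (-0.44 ± 0.51, -0.01 ± 0.56 and 0.05 ± 0.40). The BAT count of 12 was 162 by DESeq2, 42 with the library set as a term, 12 within set B and 0 within set A. It was 0 without replicate 1, 2, 3, 10 or 11, 3 without replicate 4, 22 without replicate 7 and 29 without replicate 8. The SFAT count of 11 was 400 by DESeq2, 64 with the set as a term, 13 within set A, 1053 within set B, 199 without replicate 11 and 0 without replicate 1, 2, 3, 4, 8 or 10.

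Cth-/- and Cth+/+ mice on the control diet differed in 7 genes in all 3 depots. Cth, the clock activator Arntl (Bmal1; ENSMUSG00000055116, chromosome 7, 113207465 to 113314126, plus strand), the clock repressor Cry1, Dtx4 and Osgin1 were lower in Cth-/- mice. The clock output genes Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203, plus strand) and Tef were higher. Dbp rose by 2.58 ± 0.30 in BAT, 2.45 ± 0.18 in SFAT and 2.03 ± 0.29 in EFAT, and Arntl changed by -1.28 ± 0.24 in BAT, -1.30 ± 0.17 in SFAT and -1.44 ± 0.11 in EFAT. With the library set as a term the changes of Arntl, Cry1, Dbp and Tef passed in BAT and SFAT, and in EFAT that of Arntl alone (-1.498), with Dbp at 2.15, Tef at 1.29 and Cry1 at -0.86. Arntl in EFAT was 36.4 ± 1.67 CPM in Cth+/+ mice on the control diet, 24.3 ± 1.30 on the cystine-free diet, 13.4 ± 1.47 in Cth-/- mice on the control diet and 7.02 ± 1.03 on the cystine-free diet. The circadian list had 6 higher and 2 lower of 17 in BAT, 5 and 3 in SFAT and 2 and 2 in EFAT (adjusted over the list alone, 8 and 2, 9 and 5, 7 and 4). As a list it was higher by camera in BAT (adjusted p = 0.0013; adjusted p = 0.20 with an estimated correlation), SFAT (7.6e-09; adjusted p = 0.042 with an estimated correlation) and EFAT (5.7e-04; adjusted p = 0.40 with an estimated correlation).

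**Figure D5:**
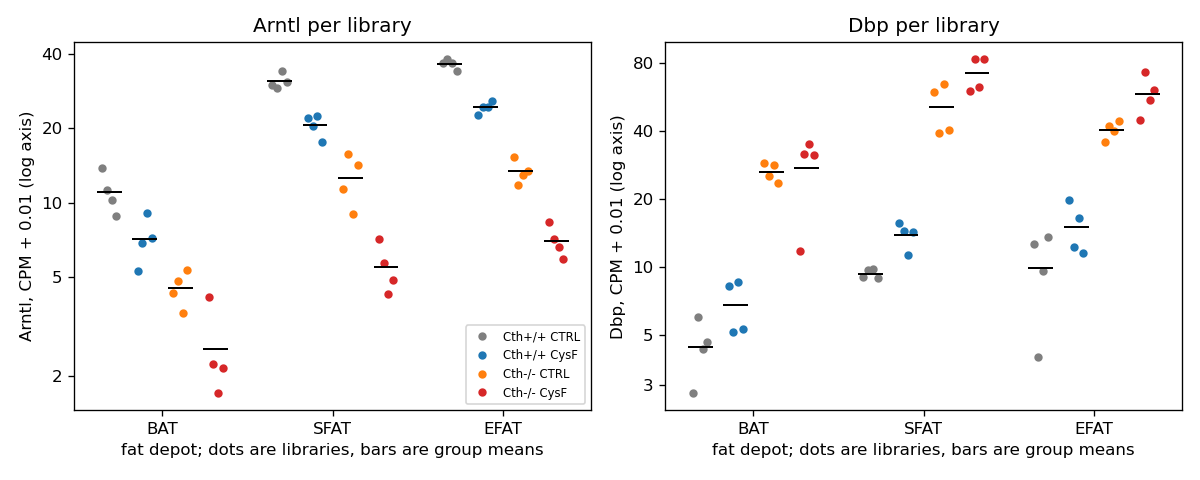
Arntl (left) and Dbp (right) in each library, as CPM with 0.01 added on a log axis, by depot and group; dots are libraries and bars are group means. In EFAT mean Arntl was 36.4, 24.3, 13.4 and 7.02 CPM and mean Dbp 9.91, 15.0, 40.5 and 58.4 CPM in Cth+/+ control, Cth+/+ cystine-free, Cth-/- control and Cth-/- cystine-free mice.

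In BAT on the control diet 305 genes differed by genotype (188 higher, 117 lower in Cth-/-). The stress-response transcription factor Atf4 (-1.29 ± 0.18), the hormones Fgf21 (-3.01 ± 0.43) and Gdf15 (-2.58 ± 0.50) and the ATF4 target Trib3 (-1.40 ± 0.30) were lower in Cth-/- mice. ATF4 target genes fell in 6 of 37 cases (adjusted over the list alone, 8; camera adjusted p = 3.4e-08, adjusted p = 0.11 with an estimated correlation). Aminoacyl-tRNA synthetase genes fell in 4 of 20 (adjusted over the list alone, 9; camera adjusted p = 2.0e-08, adjusted p = 0.38 with an estimated correlation). They included Yars (-0.79 ± 0.13) and Cars (-0.73 ± 0.17). The bicarbonate transporter Slc4a4 (2.63 ± 0.44), Mt2 (2.22 ± 0.41), Cyp2e1 (1.92 ± 0.41), Per2 (1.84 ± 0.40), Slc27a2 (1.55 ± 0.33), Klf15 (1.38 ± 0.21) and Usp2 (1.32 ± 0.27) were higher. Dusp8 (-2.42 ± 0.39), Tubb2a (-2.34 ± 0.36), Lrtm1 (-1.79 ± 0.37), Prune2 (-1.64 ± 0.34), Fer1l6 (-1.38 ± 0.23) and E2f2 (-1.36 ± 0.32) were lower. Fer1l6 followed the muscle list over the BAT libraries. In SFAT 17 genes passed (7 higher, 10 lower). Of these Per2 (1.71 ± 0.28), Per3 (1.30 ± 0.14), Nr1d2 (1.1997 ± 0.13), Slc5a6 (0.96 ± 0.14) and Abca1 (0.67 ± 0.12) were higher and Npas2 (-1.62 ± 0.23), E2f2 (-1.58 ± 0.24) and Grk5 (-0.72 ± 0.11) lower. In EFAT 8 passed (3 higher, 5 lower), with Gpr160 beside the shared genes (0.69 ± 0.11). Cholesterol synthesis genes had medians of -0.48, -0.74 and -0.76 in BAT, SFAT and EFAT with 0 members past the test over all genes or adjusted over the list alone (camera adjusted p = 2.5e-06, 9.5e-12 and 9.8e-17; adjusted p = 0.42, 0.35 and 0.53 with an estimated correlation). DESeq2 gave 792, 102 and 35 genes in BAT, SFAT and EFAT, and a fit of only the 2 groups compared 202, 13 and 3. In BAT the count was 741 with the library set as a term, 1095 within set A, 1 within set B, 183 with the muscle score as a covariate and 723 without the doubted libraries. In SFAT it was 1411 within set A and 2 within set B, and in EFAT 3 with the set as a term and 0 within each set, where 1 of the groups had a single library. Leaving out single replicates gave 32 to 354 genes in BAT (354 without replicate 14, 32 without replicate 1, 70 without 2, 81 without 3, 74 without 4, 44 without 13 and 65 without 15). In SFAT 11 genes passed without replicate 1 or 14, and in EFAT 2 without replicate 1, 13 or 15, 3 without replicate 3 or 14 and 5 without replicate 2 or 12.

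On the cystine-free diet the genotypes differed in 4589 genes in BAT (2100 higher, 2489 lower in Cth-/-), 6213 in SFAT (2997 and 3216) and 6841 in EFAT (3459 and 3382). In BAT Ucp1 was 1.07 ± 0.22 higher, Cyp2b10 5.32 ± 0.42, Acot1 3.99 ± 0.77, Pnpla2 0.90 ± 0.13 and Adipoq 0.63 ± 0.14. Lep (-4.52 ± 0.61), Fgf21 (-1.99 ± 0.44), Gdf15 (-2.20 ± 0.54), Atf4 (-0.63 ± 0.18), Ddit3 (-0.69 ± 0.26) and Scd1 (-1.31 ± 0.28) were lower. Other large differences in BAT were Hcn2 (2.91 ± 0.35), Pbld2 (2.85 ± 0.39), Inmt (2.75 ± 0.34) and Myrip (2.75 ± 0.22) on the higher side. On the lower side were Mki67 (-6.32 ± 0.67) and Fer1l6 (-5.11 ± 0.29), which followed the muscle list over the BAT libraries. Extracellular matrix genes were lower in 27 of 33 cases and higher in 1 (adjusted over the list alone, 27 and 1; camera adjusted p = 1.6e-31, adjusted p = 0.052 with an estimated correlation; Col3a1 -3.97 ± 0.24). Cholesterol synthesis genes were lower in 17 of 22 with 1 higher (adjusted over the list alone, 18 and 1; adjusted p = 0.40 with an estimated correlation; Mvd -2.30 ± 0.34). Interferon genes were lower in 19 of 20 (adjusted over the list alone, 19; adjusted p = 0.44 with an estimated correlation; Mx1 -4.43 ± 0.93). Muscle genes were lower in 18 of 18 cases (adjusted over the list alone, 18; median -4.63, adjusted p = 0.42 with an estimated correlation; Casq1 -6.54 ± 1.00), and with their score as a covariate 1424 genes passed in BAT. Within library set A 4691 passed, within set B, with 1 library of Cth-/- mice, 458, and without the doubted libraries 4324.

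In SFAT on the cystine-free diet Ucp1 (6.98 ± 1.23), Slc27a2 (6.63 ± 0.80), the fatty acid-binding protein Fabp3 (6.41 ± 1.03), Cyp2b10 (5.31 ± 0.60), Acsm3 (4.86 ± 0.40), Perm1 (4.70 ± 0.65) and Elovl3 (4.58 ± 0.77) were higher in Cth-/- mice. So were Dio2 (4.08 ± 0.68), Cidea (3.21 ± 0.41), Ppargc1a (1.80 ± 0.23), Chac1 (1.63 ± 0.28), Asns (1.00 ± 0.13), Pnpla2 (1.45 ± 0.13) and Lipe (0.64 ± 0.16). Thermogenic genes were higher in 17 of 22 cases (adjusted over the list alone, 17; median 2.78, camera adjusted p = 5.5e-11, adjusted p = 0.25 with an estimated correlation). Oxidative phosphorylation genes were higher in 56 of 66 (adjusted over the list alone, 59; adjusted p = 0.38 with an estimated correlation). Fatty acid oxidation genes were higher in 25 of 29 with 1 lower (adjusted over the list alone, 25 and 1; adjusted p = 0.15 with an estimated correlation). Extracellular matrix genes were lower in 30 of 33 (adjusted over the list alone, 31; camera adjusted p = 2.4e-36, adjusted p = 0.014 with an estimated correlation; Col3a1 -4.98 ± 0.33, Col1a1 -4.69 ± 0.47). Proliferation genes were lower in 21 of 22 (adjusted over the list alone, 21; adjusted p = 0.26 with an estimated correlation; Mki67 -4.36 ± 0.50). Cholesterol synthesis genes were lower in 18 of 23 (adjusted over the list alone, 19; adjusted p = 0.66 with an estimated correlation; Sqle -2.17 ± 0.41). Prnd (-5.64 ± 1.02), Plppr4 (-4.72 ± 0.83), Mogat2 (-4.56 ± 0.81) and Lep (-2.43 ± 0.59) were also lower. Within set A 5537 genes passed in SFAT, within set B, with 1 library of Cth-/- mice, 4697, and without the doubted libraries 5928.

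In EFAT on the cystine-free diet Acot3 (6.90 ± 0.89), Cnksr2 (6.06 ± 1.22), Zim1 (5.78 ± 0.63), the imprinted gene Peg3 (4.13 ± 0.58), Chac1 (2.16 ± 0.31), Ppargc1a (1.45 ± 0.36) and Pnpla2 (1.03 ± 0.14) were higher in Cth-/- mice. Mogat2 (-6.88 ± 1.07), Hephl1 (-6.53 ± 1.38), Ccl8 (-4.99 ± 0.61), Apln (-4.53 ± 0.68), Lep (-3.25 ± 0.44), Fasn (-2.26 ± 0.66) and Scd1 (-1.10 ± 0.35) were lower. Cholesterol synthesis genes were lower in 22 of 23 cases (adjusted over the list alone, 22; median -2.08, camera adjusted p = 2.3e-13, adjusted p = 0.60 with an estimated correlation; Insig1 -3.20 ± 0.52). Lipogenic genes were lower in 18 of 24 with 2 higher (adjusted over the list alone, 18 and 3; adjusted p = 0.65 with an estimated correlation; Acly -3.51 ± 0.78). Oxidative phosphorylation genes were lower in 32 of 66 (adjusted over the list alone, 44; adjusted p = 0.78 with an estimated correlation). Proliferation genes were lower in 18 of 22 (adjusted over the list alone, 21; adjusted p = 0.65 with an estimated correlation). Cidea (-3.02 ± 0.98) and Dio2 (-3.94 ± 0.83) were lower in Cth-/- mice, as was Elovl3, and replicate 11 of the Cth+/+ group held 5168 Ucp1 reads in EFAT. Without it Cidea was at -5.5e-04 (adjusted p from 0.011 to 1.0 over 16 alternatives) and did not pass, as without replicate 17 or 20, while Elovl3 at -4.70 and Dio2 at -2.63 did. With the library set as a term 3613 genes passed in EFAT in place of 6841, within set A (1 library of Cth-/- mice) 85 and without the doubted libraries 5510; set B held no Cth+/+ library on this diet, so it gave no value.

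The interaction test asked which genes responded to the diet differently in the genotypes. In SFAT it passed for 3600 genes (1554 with a higher and 2046 with a lower log2 change in Cth-/- mice). Among them were Ucp1 (5.05 ± 1.43, adjusted p = 0.020), Dio2 (3.85 ± 0.92), Cidea (2.68 ± 0.55), Elovl3 (3.08 ± 1.01), Ppargc1a (1.62 ± 0.32), Chac1 (1.66 ± 0.39), Asns (1.16 ± 0.19) and Pnpla2 (1.23 ± 0.18). Oxidative phosphorylation genes were higher in 56 of 66 cases (adjusted over the list alone, 60; median 1.08, camera adjusted p = 4.7e-29, adjusted p = 0.26 with an estimated correlation). Thermogenic genes were higher in 15 of 22 (adjusted over the list alone, 16 higher and 1 lower; adjusted p = 0.28 with an estimated correlation). Extracellular matrix genes were lower in 25 of 33 (adjusted over the list alone, 30; camera adjusted p = 3.8e-43, adjusted p = 0.014 with an estimated correlation; Col1a1 -5.51 ± 0.61). The largest differences in SFAT were Cyp2b10 (5.09 ± 0.95), Acsm3 (4.63 ± 0.50), Lgr6 (4.12 ± 1.14) and Cish (3.97 ± 0.77) on the higher side. On the lower side were the B cell genes Ighg2b (-8.56 ± 2.27), Cr2 (-6.92 ± 2.15), Cd22 (-5.79 ± 1.65) and Cd79a (-5.76 ± 1.86). Over the alternatives the call ended in 11 of 24 for Cr2, 13 of 25 for Cd79a, 5 of 25 for Cd22 and 2 of 24 for Ighg2b. Without replicate 14 Cr2 (-3.79), Cd22 (-3.77) and Cd79a (-3.08) did not pass, nor without replicate 10 (-4.22, -4.54 and -4.03). The Cr2 call also ended without replicate 1, 2, 3, 16, 17 or 18 and the Cd79a call without replicate 1, 2, 7, 16, 17 or 20. Ighg2b was at -3.53 without replicate 10 and did not pass within set A (-2.81) or set B (-13.13). Within library set A 2122 genes passed, within set B (1 library of Cth-/- mice on the cystine-free diet) 2840, by DESeq2 4210, with the set as a term 4199 and without the doubted libraries 3583. Ucp1 did not pass without replicate 4 (3.93) or within set B (5.62; adjusted p from 0.0036 to 0.098 over 25 alternatives).

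In BAT the interaction passed for 932 genes (305 higher, 627 lower). Ucp1 (0.93 ± 0.31, adjusted p = 0.089), Pnpla2 (0.59 ± 0.18, 0.065) and Chac1 (1.21 ± 0.46, 0.13) did not pass. Cyp2b10 (5.55 ± 0.58), Inmt (3.22 ± 0.47), Gfra1 (2.69 ± 0.41), the prolactin receptor Prlr (2.32 ± 0.37) and Hcn2 (2.29 ± 0.50) were highest. Mki67 (-5.97 ± 0.82), Casq1 (-5.51 ± 1.23), Ckmt2 (-5.27 ± 1.45), Pvalb (-4.31 ± 1.199) and Lep (-3.33 ± 0.77) were lower. Extracellular matrix genes were lower in 17 of 33 cases and higher in 1 (adjusted over the list alone, 23 and 1; camera adjusted p = 2.1e-40, adjusted p = 0.051 with an estimated correlation; Col1a1 -3.85 ± 0.46). In EFAT 1792 genes passed (870 higher, 922 lower). Chac1 (2.15 ± 0.42), Pnpla2 (1.09 ± 0.20), Acsm3 (5.05 ± 0.72), Teddm2 (5.17 ± 1.14), Il22ra2 (4.77 ± 0.83) and Zim1 (4.42 ± 0.80) were higher, and Mogat2 (-5.79 ± 1.28), Ccl8 (-5.20 ± 0.77), Odf3l1 (-4.26 ± 0.91), Wfdc21 (-3.99 ± 0.81), Col15a1 (-3.82 ± 0.45) and Lep (-2.94 ± 0.58) lower. Extracellular matrix genes were lower there in 18 of 33 cases and higher in 1 (adjusted over the list alone, 20 and 1; adjusted p = 0.25 with an estimated correlation). The BAT count was 1484 by DESeq2, 2 within library set B (1 library of Cth-/- mice on the cystine-free diet), 406 with the muscle score as a covariate and 504 without the doubted libraries. The EFAT count was 2862 by DESeq2, 1002 without the low-count filter, 57 with the set as a term, 3 within set A (2 groups of 1 library) and 536 without the doubted libraries. Leaving out single replicates moved the BAT count to 488 (replicate 3), 489 (4), 575 (14), 516 (17) and 554 (18). It moved the EFAT count to 1045 (replicate 1), 714 (4), 1130 (8), 715 (12), 789 (14), 2924 (15), 3414 (16), 840 (17) and 822 (20).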

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

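The Zic1 test, the tests of replicate 11 and the collection-time test were chosen after the results they concern were seen, as were the fits with the library set as a term or without the doubted libraries. The values in this part stand out because a single library lay far from the others of its group, or because a test of the difference between groups passed.

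Several quantities were tested in each group of 4 libraries, 135 tests in all. In 11 of these a library's gap to the next exceeded Dixon's 95% critical value, against 6.75 expected, since chance gives about 1 in 20. Tests on the same libraries are not independent, so the expected number is a rough guide. In BAT, Cyp2b10 was 3.61 CPM in replicate 14 (1.06 to 1.32 in the others of its group), Dbp 11.8 CPM in replicate 16 (31.3 to 34.9) and the mitochondrial share 37.5% in replicate 20 (25.5 to 26.9). In SFAT, Ucp1 was 19.4 CPM in replicate 10 (0.991 to 3.64) and the mitochondrial share 31.3% in replicate 20 (10.6 to 11.5). In EFAT, Ucp1 was 182.9 CPM in replicate 11 (0 to 0.0467), 3.82 CPM in replicate 15 (0.0283 to 0.237) and 1.57 CPM in replicate 17 (0.0954 to 0.235). Cyp2b10 was 2.76 CPM in EFAT of replicate 11 (1.12 to 1.202), Lep 44.2 CPM in EFAT of replicate 20 (192.5 to 205.7) and Fkbp5 258.1 CPM in EFAT of replicate 16 (390.3 to 410.1).

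The response to the diet differed between the genotypes in 932 genes in BAT, 3600 in SFAT and 1792 in EFAT. Among 100 splits of the libraries the real count was the highest in SFAT (next 1442) and EFAT (next 1305), 1 of 100 in each. A split dealt all libraries of a depot anew over the groups, which moves the effects of genotype and diet too. A split may keep part of these effects. The splits therefore do not all stand for no effect, and cannot decide on the interaction alone. These splits do not exclude the library set: with the set as a term the count was 4199 in SFAT but 57 in EFAT, where the sets are spread unevenly over the groups, so the EFAT count may follow the set. In BAT (1250 with the set as a term) 3 of 100 splits, the real one among them, gave at least the real count. The highest, with 2500 genes, put replicates 16, 17, 18 and 20 (Cth-/- cystine-free) and 1, 2, 3 and 4 (Cth+/+ control) on opposite sides. The next, with 2073 genes, did so with the Cth-/- and the Cth+/+ libraries (7, 8, 10 and 11) on the cystine-free diet. The EFAT split with 1305 genes was the same deal as the one with 2500. These splits thus hold part of the real effects of genotype and diet. Between depots the response differed in 397 genes for SFAT and BAT, 2976 for EFAT and BAT and 804 for EFAT and SFAT. The highest other splits gave 0, 802 and 3. The split with 802 follows the library set in EFAT. With the set as a term the EFAT counts were 1753 against BAT and 238 against SFAT. The real split alone, 1 of 35, gave its count in each. These splits exchanged diet labels within Cth-/- mice in all depots at once, so a diet effect that all depots share would be lost too. They thus cannot decide on a difference between depots.

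For the diet in Cth-/- mice the real split alone (1 of 35) gave its count in BAT (2617; highest other 4), SFAT (4208; 0) and EFAT (4976; 3123). The EFAT split with 3123 genes parts replicates 12, 13, 14 and 16 from the rest, which is the library set, and with the set as a term the real comparison gave 3117. For the diet in Cth+/+ mice the real split alone (1 of 35) gave its count of 12 genes in BAT. The highest other, 7, came from the split of replicates 1, 2, 10 and 11 that is the library set. With the set as a term 42 genes passed. The count was 0 without replicate 1, 2, 3, 10 or 11. As 1 of 35 is the smallest share possible and shares were not adjusted over the comparisons, chance stays open for this count. In SFAT chance was not excluded, as 2 of 35 splits gave as many as the 11 genes. The other split, with 1011 genes, parts replicates 1, 2, 8 and 11 from the rest and is the library set, and with the set as a term the real comparison gave 64. In EFAT the real count was 0 by edgeR (678 of 17248 genes at an unadjusted p under 0.05, 21 by DESeq2), so all 35 splits gave as many, the highest 1. For the genotype on the control diet the real split alone (1 of 35) gave its count in BAT (305), SFAT (17) and EFAT (8). The highest other counts were 286, 1 and 1. The 286 came from the split of replicates 1, 2, 12 and 14 that is the library set, and with the set as a term 741 genes passed. On the cystine-free diet the real split alone (1 of 35) gave its count in BAT (4589), SFAT (6213) and EFAT (6841). There the highest other counts were 1, 1376 and 9.

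Brown-fat-type genes were higher in SFAT of Cth-/- mice on the cystine-free diet. The library set as the whole cause was excluded: 129 of the BAT-enriched genes rose with the set as a term, against 117 without it. Brown fat tissue carrying Zic1 as the sampled BAT does was excluded by Zic1, which gained 0.595% of its BAT level where Ucp1 gained 14.0%; its mean was 0.135 ± 0.048 CPM, below the 0.372 CPM that 0.25 of the Ucp1 share would need. Brown fat tissue in the dissected samples stays open, since 6 BAT-specific genes gained a median of 12.0% (quartiles 7.76 and 14.9%), 0.856 times the share of Ucp1. A response of SFAT cells to the diet without the enzyme, which the groups name, may give the same values and was not tested apart from it.

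EFAT of replicate 11 (Cth+/+ on the cystine-free diet) held transcripts of brown fat and muscle. Skeletal muscle alone was excluded by 5168 Ucp1 reads, against a median of 2 in the other 15 EFAT libraries and 122 in the next. A candidate source is brown fat tissue in the dissected sample, since 12 BAT-specific genes that do not follow muscle over the BAT libraries, without Ucp1, stood at similar shares of their BAT level (median 5.95%, upper quartile 1.47 times the lower; at most 0.702% over the other libraries of the group), with Ucp1 at 6.21% and Zic1 at 8.42%. The first form of this test, on 21 genes that held Ucp1 and muscle genes such as Ttn and Atp2a1, gave a ratio of 1.46, and 16 genes of the muscle list stood at 6.26% of their BAT level. Shares this alike do not tell whether such material entered at dissection or in a later step. No biological explanation was tested, as the pattern lies in 1 library.

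Clock genes differed by genotype on the control diet in all 3 depots. The library set was excluded as the whole cause in BAT and SFAT, where each control group held 2 libraries of set B. Of 12 calls of Arntl, Cry1, Dbp and Tef 9 held with the set as a term, 4 in BAT, 4 in SFAT and 1 in EFAT. In EFAT set B held 3 libraries of Cth+/+ and 1 of Cth-/- mice. The changes of Cry1, Dbp and Tef there were -0.89, 2.03 and 1.30 without the term and -0.86, 2.15 and 1.29 with it. They kept their size but no longer passed, so the set was not excluded for these genes. A difference in collection time between the genotypes and an effect of the genotype on the clock cannot be told apart, since both may move Arntl and Cry1 down and Dbp and Tef up, as seen in 3 of 3 depots, and the labels give no time of collection. With the diet in Cth-/- mice Arntl fell too (-0.79, -1.20 and -0.93 in BAT, SFAT and EFAT). Per1 (1.43, 1.33 and 1.60) and Per2 (1.22, 1.12 and 0.88) rose, and all these changes passed. Cry1 did not fall there (0.13, 0.81 and 0.32), and in SFAT it passed as higher (edgeR adjusted p = 0.0031). Collection time was not tested for that comparison and stays open there too.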

How the results depend on the processing

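The fits with the library set, without the doubted libraries and with a cell-type score were chosen after the data were seen; the other alternatives were planned. Of 1182 named values 995 had passed, and 250 of these passed in every alternative; of the 187 that had not, 164 passed in none. Counts within 1.5 times the value first given are not listed. Except where fewer libraries or fewer tested genes explain it, the cause was not tested.

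With DESeq2 the counts were 162 (BAT) and 400 (SFAT) for the diet in Cth+/+ mice, with 21 in EFAT; 792, 102 and 35 for the genotype on the control diet in BAT, SFAT and EFAT; and 1484 and 2862 for the interaction in BAT and EFAT. It gave 623 genes for SFAT against BAT and 1213 for EFAT against SFAT. Without the low-count filter 19 genes passed in BAT and 7 in SFAT for the diet in Cth+/+ mice, 1002 for the EFAT interaction, and 191, 1949 and 528 for SFAT against BAT, EFAT against BAT and EFAT against SFAT. RLE scaling gave 18 in SFAT for the diet in Cth+/+ mice. A fit of only the 2 groups compared gave 0 and 3 there in BAT and SFAT, and 202 and 3 for the genotype on the control diet in BAT and EFAT.

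With the replicate number as a block 892 genes passed for SFAT against BAT, 2234 for EFAT against SFAT and 4231 for EFAT against BAT.

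With the library set as a term 42 genes passed in BAT and 64 in SFAT for the diet in Cth+/+ mice, 741 in BAT and 3 in EFAT for the genotype on the control diet, 3117 for the diet in Cth-/- mice, 3613 for the genotype on the cystine-free diet and 57 for the interaction in EFAT, and 1753 and 238 for EFAT against BAT and SFAT. Within a set the libraries are fewer, and these groups held only 1: Cth-/- cystine-free in set B of BAT and SFAT and in set A of EFAT, Cth+/+ control in set A of EFAT and Cth-/- control in set B of EFAT. Within set A BAT gave 0 for the diet in Cth+/+ mice and 1095 for the genotype on the control diet, SFAT 1411 for the latter and 2122 for the interaction, and EFAT 65 for the diet in Cth-/- mice, 0 and 85 for the genotype on the control and cystine-free diets and 3 for the interaction. Within set B BAT gave 333 for the diet in Cth-/- mice, 1 and 458 for the genotype on the control and cystine-free diets and 2 for the interaction, SFAT 1053 for the diet in Cth+/+ mice and 2 for the genotype on the control diet, and EFAT 219 for the diet in Cth-/- mice and 0 for the genotype on the control diet. Set B gave no value for the other EFAT comparisons, as it holds no Cth+/+ library on the cystine-free diet.

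Without the doubted libraries BAT gave 0 for the diet in Cth+/+ mice, 723 for the genotype on the control diet and 504 for the interaction, SFAT 6 for the diet in Cth+/+ mice, and EFAT 4 for the genotype on the control diet and 536 for the interaction. The depot differences were then 157, 1731 and 468 for SFAT against BAT, EFAT against BAT and EFAT against SFAT. With a cell-type score BAT gave 862, 4, 183, 1424 and 406 for the diet in Cth-/- mice, the diet in Cth+/+ mice, the genotype on the control and cystine-free diets and the interaction, and SFAT 0 for the diet in Cth+/+ mice.

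Signs reversed in 13 cases. With the muscle score, Atp2a1 was 0.25 for the diet in Cth-/- mice and 0.59 for the genotype on the cystine-free diet in BAT, and Myh7 1.04 for the latter, as the score holds muscle genes. Within set A, Asns passed as higher (0.62, adjusted p = 0.027) for the diet in BAT of Cth-/- mice. In EFAT set A gave Ehhadh -0.14, Emcn -0.033 and Zfp36 -0.020 for that diet, Emcn -0.28 and Zfp36 -0.37 for the genotype on the cystine-free diet, and Emcn -0.19 for the interaction. In EFAT of Cth+/+ mice the median diet change of nuclear oxidative phosphorylation genes was -0.077 with the set as a term (camera adjusted p = 0.029). With each replicate left out this median ran from -0.026 (without replicate 11) to 0.25. The median of extracellular matrix genes was -0.011 without the doubted libraries. For these lists the direction that reversed is that of camera.

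Of the list tests past camera, 4 also passed with an estimated correlation. Fry passed 121 list tests, of which 107 were past camera. BAT-enriched genes in SFAT, with a mean of 1.02, no longer passed with an estimated correlation (p = 0.050), and in EFAT a list of 100 genes passed, with a mean of 0.27 (p = 0.044; 0.19 to 0.99 over the other alternatives).

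Leaving out each replicate in turn gave 1695 to 2431 genes for the diet in BAT of Cth-/- mice and 2962 to 5886 in EFAT, and 0 to 29 and 0 to 199 for the diet in BAT and SFAT of Cth+/+ mice. The genotype on the control diet gave 32 to 354 in BAT, 11 to 17 in SFAT and 2 to 6 in EFAT, and the interaction 488 to 965 in BAT and 714 to 3414 in EFAT. The depot differences ran from 106 to 294 (SFAT against BAT), 1075 to 3828 (EFAT against BAT) and 178 to 983 (EFAT against SFAT).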

Other observations

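The lists in this part were fixed before the data were examined, and no test was added for them.

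In Cth-/- mice the diet raised UCP1-independent cycle genes in 2 of 12 cases in SFAT and lowered 3 (adjusted over the list alone, 2 and 3; median 0.11). In BAT 5 rose and 5 fell of 12, and in EFAT 0 and 4 of 12. Glycolysis genes had medians of 0.24, 0.52 and -0.69 in BAT, SFAT and EFAT, with 5, 8 and 1 higher and 0, 1 and 5 lower. NRF2 target genes, which respond to oxidants, had medians of -0.19, 0.06 and -0.08, with 0, 3 and 5 higher and 6, 2 and 7 lower. Unfolded protein response genes had medians of -0.13, -0.12 and -0.25 (higher 1, 2 and 1, lower 0, 3 and 8). Immediate early and heat shock genes had medians of 0.07, 0.01 and 0.38 (higher 0, 0 and 2, lower 0, 0 and 0); in BAT their mean was -0.02 and camera pointed down, without passing.

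Among other cell types in the same comparison, endothelial genes had medians of 0.01, 0.14 and 0.10 (lower 0, 0 and 0, higher 1, 0 and 2). Erythroid genes had medians of -0.78, -0.12 and -0.41, and Schwann cell and nerve genes -0.32, 0.25 and 0.30. In SFAT and EFAT, where at least 5 members were tested, T cell genes had medians of -1.27 and 0.06, neutrophil genes -1.07 and -0.48 and mesothelial genes 1.30 and -0.00.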
